A study of Mus musculus with 3 samples.

How the data were processed

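Crypts of the small intestine were harvested from mice of 2-3 months, digested with TrypLE (3x) for 1 h and processed with the 10x Genomics Chromium 3' kit, version 3, with 4000-5000 cells harvested per library according to the labels. The deposited matrices hold, per gene and barcode, a count of unique molecular identifiers (UMIs) as the authors' Cell Ranger run wrote it, in unit count. The submitters' processing notes name Cell Ranger 1.3.0, whereas the file headers name Cell Ranger 3.0.2 for the control and KO libraries and 3.1.0 for the rescue library. The genome build is not given in the sources used here. Of the 28692 gene identifiers 28416 (99.04%) were found in GENCODE vM21, from which the coordinates were taken. Groups followed the GEO labels, with 1 library each for control, KO and rescue. The tables held 6152, 4786 and 3449 barcodes, with at least 500, 590 and 500 UMIs each.

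Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, which left 1595, 2036 and 1897. The mitochondrial limit alone removed 66.3%, 54.1% and 38.3% of barcodes. Doublets were scored against 2 simulated doublets per cell within each library, and the highest scores were removed at 0.8% per 1000 cells, which removed 20, 33 and 29. Median depth of the kept cells was 5551, 27639 and 5950 UMIs and median gene number 2064, 4249 and 2061. Immune-like cells were shallow and made up more of the control and rescue libraries, and epithelial cells were closer in depth. Counts were scaled to a common total and log-transformed, 2000 variable genes were reduced to 40 principal components over all 3 libraries without batch correction, and cells were clustered by the Leiden method on a shared-neighbour graph of 15 neighbours at resolution 1.0, which gave 28 clusters.

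Clusters were named from 11 fixed marker lists. A class was considered where at least 3 markers, and at least 20% of its list, were 2-fold over the other cells with at least 10 UMIs. In order of that percentage, the first class with as many markers among the 10 leading genes as any other class gave the name. Clusters of low depth for their library also needed a marker among the 10 leading genes. Epithelial clusters had more *Epcam* than *Ptprc* CPM and no immune, stromal, endothelial or erythroid name. This naming rule and the rule for epithelial clusters were set after the data were examined, because an earlier score misnamed T cells. All other choices, the gene lists, the comparisons and the rule for named genes were fixed before the data were examined, apart from the alternatives and tests said below to be chosen later. Endothelial and erythroid clusters were not found, and stromal-like and endothelial markers were too rare in progenitors to be measured.

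UMIs were summed over the progenitors (ISC-like and TA-like cells; 173, 310 and 226 cells with 6338909, 16361851 and 15679148 UMIs) and over all epithelial cells (19971232, 61519489 and 43821782 UMIs), and given as CPM, the UMIs of a gene over all UMIs, scaled to a fixed total. Progenitors were the main population because Cre was driven from a stem cell gene. Ratios had conditional exact binomial intervals, and CPM exact Poisson intervals. At 20 UMIs such an interval is wide, and a gene of 50 CPM in progenitors is counted far more often than that in each library. For each of 28 gene lists and the marker lists, the median log2 ratio was taken with a pseudocount of 1 CPM over members with at least 20 UMIs in 1 of the 2 libraries. It was placed among 10000 random lists whose members were drawn from the 100 genes nearest in expression. Where members were at 0 in 1 library, the median was also taken with those at a floor of 3 counts over the group, called the bound. Named genes had at least 50 CPM in 1 of 2 libraries and were the 10 highest and 10 lowest by log2 ratio in progenitors, and the 5 highest and 5 lowest in epithelium, with intervals excluding 1. Mitochondrial, ribosomal protein, sex-linked, *Defa* and differentiated-cell marker genes were left out in progenitors. Named always were the targeted genes, the EGF ligands and receptors, *Lgr5*, *Olfm4*, *Ascl2* and *Mki67*. Examples of a list were its 2 highest and 2 lowest members. For shares of cells with a UMI each cell was thinned to 2000 UMIs, which left out 96, 120 and 108 epithelial cells.

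The ratio step was tested on simulated data for KO against control with 9822 genes. True folds of 4, 2, 1, 0.5 and 0.25 gave median ratios of 4.03, 1.98, 1.00, 0.497 and 0.254, after correction for the composition change known in the simulation. Intervals held the truth, shifted by the same change, for 98%, 100%, 95.4%, 98% and 94% of genes. Counts were drawn as Poisson, so the simulation covers counting error and does not test bias from composition. Of 200 unchanged lists 4% fell outside the central 95% of random lists, and 20 of 20 raised lists lay above it. Every member of a raised list had a true fold of 2 or 4 and was drawn at random. Smaller shifts and lists of genes that vary together were not tested. Alternatives covered cell filters, doublets, resolution, components, joint or separate clustering, the genes used to cluster, scaling, pseudocount, count minimum, class mix and thinning. The median log2 ratio of all genes in progenitors was −0.08 for KO over control, and −0.21 and −0.20 with the 2 other scalings. In epithelium it was −0.26, −0.46 and −0.43 for KO over control and 0.26, 0.35 and 0.23 for rescue over KO, and the directions given are relative to total UMIs. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.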

Results

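Single-cell RNA sequencing (10x Genomics Chromium, 3' version 3 chemistry) was carried out on small intestinal crypts of adult C57BL/6 mice. All animals carried a tamoxifen-inducible Cre recombinase under *Olfm4*, a gene expressed in crypt base stem cells. There were 3 libraries, with 1 library per genotype. The control had 1 floxed and 1 wild-type *Cdc42* allele, the KO had 2 floxed *Cdc42* alleles, and the rescue had 2 floxed *Cdc42* alleles, 2 floxed *Yap1* alleles and 1 floxed *Wwtr1* allele. CDC42 organises apical-basal polarity and actin, and YAP (*Yap1*) and TAZ (*Wwtr1*) are co-activators controlled by the Hippo pathway. The deposited tables held 58433966 UMIs over 6152 barcodes in the control, 85525811 over 4786 in the KO and 64355665 over 3449 in the rescue. Median depth was 5944.5, 7273.5 and 5853 UMIs per barcode, and the median mitochondrial share was 52.3%, 22.7% and 14.2%. After the cell limits and doublet removal 1575, 2003 and 1868 cells remained. Of these 616, 1642 and 1013 were epithelial, with median depths of 30095.5, 38781.5 and 40120 UMIs. Because each genotype had 1 library, no difference was tested, and all values describe these libraries only. Intervals are exact 95% intervals and cover counting error only.

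*Cdc42* (ENSMUSG00000006699, chromosome 4: 137319696-137357720) was not lower in the KO library. In all epithelial cells it stood at 246 CPM (239-252) in the control, 386 (381-390) in the KO and 390 (384-396) in the rescue. In the progenitors, the pooled ISC-like and TA-like cells, it stood at 250, 344 and 322 CPM, a KO over control ratio of 1.37 (1.3-1.45). *Yap1* (ENSMUSG00000053110, chromosome 9: 7931999-8004596) stood at 26.3, 24.7 and 20.5 CPM in epithelium and 41.5, 29.5 and 27.2 CPM in progenitors. *Wwtr1* (ENSMUSG00000027803, chromosome 3: 57455649-57575910) stood at 7.31, 13.4 and 2.92 CPM in epithelium. In progenitors it stood at 13.3, 13.5 and 5.10 CPM, which was 2.64-fold (2.03-3.45) lower in the rescue than in the KO. The KO over control ratio of *Wwtr1* in progenitors lay near 1 and turned with the scaling, and that of *Yap1* turned to a log2 of 0.42 under the stricter cell filter. Which exons the floxed alleles delete is not given in the sources used here, and a 3' tag outside the deleted part checks nothing. Control, KO and rescue therefore each stand for the library labelled so, and each direction below rests on those labels.

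ISC-like cells, the class named from stem cell markers such as *Lgr5* and *Olfm4*, were nearly absent from the KO and rescue libraries. They made up 21.8% (18.6-25.2) of control epithelial cells, 134 cells, against 0.183% (0.0377-0.533) in the KO, 3 cells, and 0.197% (0.0239-0.711) in the rescue, 2 cells. Names were given to whole clusters, so this share does not count every cell with these genes. With cells thinned to 2000 UMIs, *Olfm4* was found in 37.6% of control, 5.18% of KO and 14.6% of rescue progenitors. TA-like cells, the rapidly dividing daughters of stem cells, made up 6.33% (4.54-8.55), 18.7% (16.8-20.7) and 22.1% (19.6-24.8). Enterocyte-like cells, the absorptive lineage, made up 24.8% (21.5-28.4), 49.6% (47.1-52.0) and 53.9% (50.8-57.0). Paneth-like cells, which make antimicrobial peptides and feed the stem cell niche, made up 7.95% (5.94-10.4) of control cells, 0 of 1642 KO cells and 1.48% (0.831-2.43) of rescue cells. Enteroendocrine-like cells, which secrete gut hormones, made up 9.74%, 1.46% and 1.97%. Goblet-like cells, which secrete mucus, made up 11.5%, 11.4% and 3.95%. Tuft-like cells, the chemosensory lineage, made up 1.3%, 0.183% and 0.296%. Immune-like cells made up 59.7%, 15.1% and 43.6% of all kept cells, and the cluster named stromal-like 1.08%, 2.80% and 1.55%. That cluster was mixed, led by plasma and mast cell genes (*Igkc*, *Jchain*, *Igha*, *Mcpt1*, *Mcpt2*) as well as the stromal *Dcn*, *Sparc* and *Col3a1*. Endothelial and erythroid clusters were not found.

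**Figure D1:**
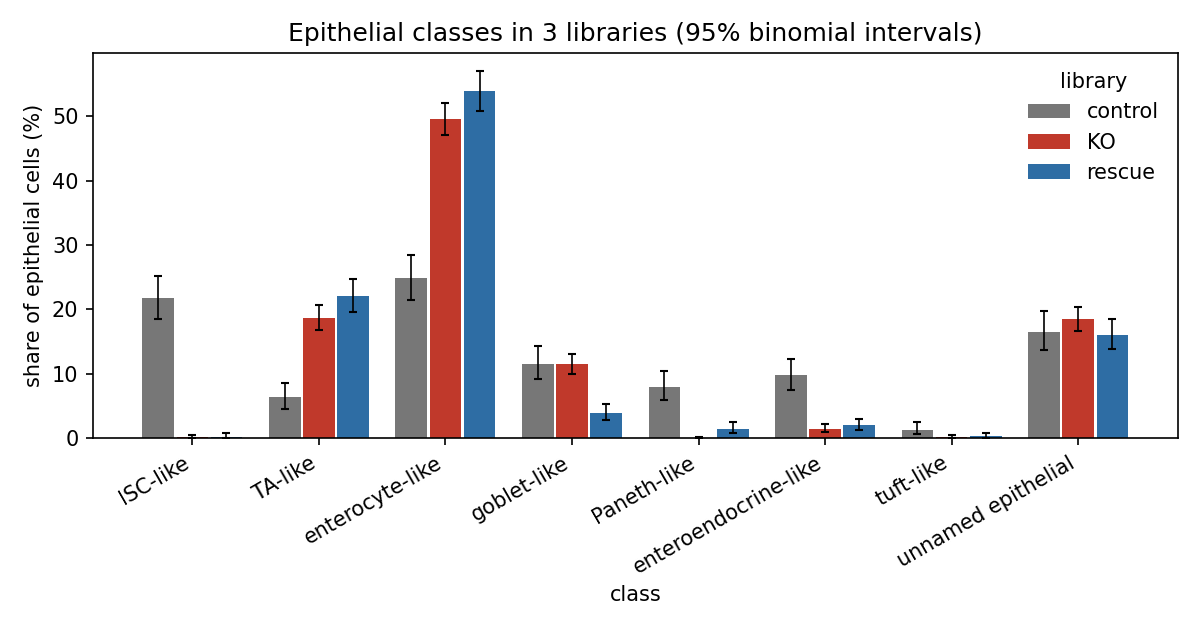
Share of each epithelial class. The vertical axis is the percent of epithelial cells, the horizontal axis the class, and colours are the control, KO and rescue libraries (1 library each). Error bars are exact binomial 95% intervals. ISC-like and Paneth-like cells are prominent in the control library only, and TA-like and enterocyte-like cells have larger shares in the KO and rescue libraries, except that the rescue enterocyte-like share lies below the control with every barcode of at least 200 genes.

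Many classes were held by clusters that came mostly from 1 library, which may be that library and not a type. Control progenitors lay mostly in cluster 13 (134 control, 3 KO and 2 rescue cells), KO progenitors in cluster 5 (4, 294 and 0) and rescue progenitors in cluster 7 (35, 13 and 224). Cluster 5 took the TA-like name with raised levels of 9 of 18 markers and was led by *Anxa1*, *Phlda2* and *Acot1*, whereas cluster 7 had raised levels of all 18. Enterocyte-like cells lay mostly in cluster 18 in the control (110 of 153 cells, with 33 in cluster 4 and 10 in cluster 6), clusters 2 and 3 in the KO (415 and 396) and clusters 4 and 6 in the rescue (272 and 274). The 4 leading genes of cluster 4 were *Ubd*, *S100g*, *Isg15* and *Zbp1*, of which *Ubd*, *Isg15* and *Zbp1* are induced by interferon or inflammation and *S100g* is a calcium-binding protein of enterocytes. Goblet-like cells lay mostly in cluster 17 in the control (69 cells) and cluster 12 in the KO (164). Immune-like cells also lay apart, in clusters 0, 9 and 23 in the control (577, 243 and 52 cells, with 1 rescue cell and 0 KO cells among them) and mostly in clusters 1, 8 and 10 in the rescue (364, 214 and 177). Clusters 11, 14, 15 and 19 were epithelial but took no class name under a rule set after the data were seen, and held 16.6%, 18.5% and 16.1% of epithelial cells. Cluster 15 (77, 12 and 35 cells, median 1633.5 UMIs) was led by the plasma cell genes *Igkc*, *Igha* and *Jchain*, so it was mixed and is part of every epithelial share and CPM. All shares rest on the 1000-UMI minimum and the 20% mitochondrial limit, which removed most control barcodes. With every barcode of at least 200 genes kept, the ISC-like share was 2.84% in the control and 1.18% in the rescue, and the enterocyte-like share of the rescue was below that of the control, 14.6% against 27.8%. The immune-like share was then 16.8% in the control, 7.23% in the KO and 26.2% in the rescue, which turned the rescue above the control. The rescue ISC-like share was 3.17% with 20 components and 2.495% without cell cycle genes in the clustering, and the control share was 0% under the stricter filter, where no cluster took that name. The KO TA-like share was near 10% under 4 other clustering choices (9.93% to 10.3%), and the control TA-like share ranged from 0.314% to 11.4%.

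Among progenitors, the genes that mark or maintain intestinal stem cells were lower in the KO than in the control library. *Lgr5*, the R-spondin receptor of crypt base stem cells, stood at 103 CPM in the control and 1.59 in the KO, 64.6-fold (43.7-99.7) lower. *Ascl2*, the transcription factor of stem cell identity, stood at 120 and 8.74 CPM, 13.7-fold (11.5-16.5) lower. *Olfm4*, a Notch-dependent stem cell gene, stood at 298 and 19.0 CPM, 15.7-fold (13.9-17.7) lower. *Lrig1*, a brake on ERBB receptors that also marks stem cells, was 4.08-fold (3.44-4.84) lower. All 18 measured ISC markers were lower, with a median log2 ratio of −2.77, at percentile 0 of 10000 random lists matched on expression. All 14 measured Wnt target genes were lower (−2.31, percentile 0), from *Cd44* (−0.38) and *Ephb2* (−0.70) to *Ascl2* (−3.64) and *Lgr5* (−5.32). *Lgr5*, *Ascl2*, *Axin2*, *Sp5*, *Znrf3* and *Tnfrsf19* belong to both the ISC and the Wnt list. The Wnt medians, here and below, are therefore not independent of the ISC markers that named the clusters. Under the stricter cell filter, which left 20 control progenitors, the Wnt median was −0.57. Genes of Notch signalling and secretory fate had a median of −1.06 (percentile 0.035), with *Notch1* at −2.36, *Sox4*, a progenitor transcription factor, at −2.77 and *Spdef*, a goblet fate factor, at 0.87. *Mki67*, a marker of cycling cells, stood at 74.8 and 156 CPM, 2.09-fold (1.89-2.31) higher in the KO. The class mix differed as well, since 134 of 173 control progenitors but 3 of 310 in the KO were ISC-like. Because clusters were named from the ISC markers, the mix cannot be told apart from the fall of these genes. In TA-like cells alone *Lgr5* was 5.98-fold (2.85-12.1), *Ascl2* 4.81-fold (3.53-6.49) and *Olfm4* 4.08-fold (3.25-5.09) lower, with medians of −1.66 for ISC markers, −0.80 for Wnt targets and −0.32 for Notch genes, and *Mki67* turned to a log2 ratio of −0.55.

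The genes furthest higher in KO progenitors included genes of the regenerative or fetal-like program of injured gut epithelium, of gastric epithelium and of host defence, beside metabolic and cytoskeletal genes. *S100a6*, a calcium-binding protein of the regenerating epithelium, stood at 17.8 CPM in the control and 2195 in the KO, 123-fold (102-149) higher. *Anxa1*, an annexin of epithelial repair, was at least 187-fold higher, and *Clu*, which marks revival stem cells, stood at 2.52 and 74.9 CPM. *Anxa10*, an annexin of gastric epithelium, was at least 348-fold higher, and *Ctse*, the gastric protease cathepsin E, at least 145-fold higher. *Sprr2a3*, a small proline-rich barrier protein, was 627-fold (214-3039) higher against 3 control UMIs. *Reg3b*, a bactericidal lectin, was 227-fold (162-330) higher, *Scd2*, a fatty acid desaturase, 179-fold (90.7-415), and *Gm766*, an uncharacterised gene, 114-fold. *Capg*, an actin capping protein, was 75.8-fold higher and *Gsta4*, a detoxifying glutathione transferase, 70.2-fold higher. *Sprr2a3*, *Gm766*, *Gsta4* and *Capg* were also among the 10 leading genes of enterocyte-like cluster 2, which held KO cells only. Levels in KO epithelium as a whole were higher for *S100a6* (4992 CPM), *Anxa10* (658) and *Ctse* (271) and lower for *Anxa1* (31.2) and *Clu* (41.1). Whether differentiated KO cells or their free RNA add to these progenitor values was not tested. Of 18 measured regenerative program genes 17 were higher, with a median of 3.73 (percentile 100), from *S100a6* (6.87) and *Anxa1* (6.49) to *Cd55* (0.53) and *Cldn4* (−0.60). Lower medians came with a pseudocount of 5 CPM (2.45), members of at least 5 UMIs (3.06), the stricter cell filter (2.90) and clustering without these genes (2.67).

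The genes furthest lower in KO progenitors included host defence, antigen presentation and signalling genes. *AY761184* and *Gm15284*, alpha-defensin genes of Paneth cells with near-identical relatives that make the read assignment uncertain, were at least 892-fold and 194-fold (137-287) lower. Control immune-like cells held them at the level of control progenitors (163 against 164 CPM and 447 against 368 CPM), so these values lie at the level of free RNA and follow the Paneth-like cells of each library. *Ceacam10*, a secreted adhesion molecule, was 298-fold lower, with 146 CPM in the control and 0.489 in the KO. *Cd74*, the MHC class II invariant chain, was 37.7-fold (28.0-51.8) lower, and *Slc27a2*, a fatty acid transporter, 38.4-fold lower. *Gas6*, a ligand of the AXL and MERTK receptors, was 25.3-fold (18.7-34.9) lower, and *Edn2* (endothelin 2), *Tnfsf10* (the death ligand TRAIL) and *Camk2n1* (a kinase inhibitor) were also among the 10 lowest. All 6 measured MHC class II genes were lower (median −2.50, percentile 0), and the interferon response genes stood near the middle of random lists (−0.28, percentile 43.2). Immune markers were also lower in these progenitors, and immune-like cells made up 59.7% of kept control cells and 15.1% of kept KO cells. Whether free RNA of immune cells adds to the MHC class II fall was not tested. Inflammation genes had a median of −0.86 (percentile 0.01), with *Ccl28*, a mucosal chemokine, at −1.49 and *Il18* at 2.64. Antimicrobial genes had a median of 1.37 (percentile 100), although *Pigr* (−1.58) and *Lcn2* (−1.42) were lower.

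The ligands and receptors of the EGF pathway were not lower or higher as a group in KO progenitors. Among ligands, *Areg* (amphiregulin) stood at 264 CPM in the control and 436 in the KO, 1.65-fold (1.57-1.74) higher, and *Ereg* (epiregulin) at 1.74 and 7.03 CPM, 4.05-fold (2.18-8.34) higher. *Btc* (betacellulin) was 2.65-fold (2.00-3.57) higher and *Tgfa* 1.92-fold higher, whereas *Hbegf* stood at 607 and 263 CPM, 2.31-fold (2.21-2.42) lower. The receptor *Egfr* was 2.29-fold (1.76-2.98) lower, its dimer partner *Erbb2* 1.37-fold higher and *Erbb3* 1.63-fold lower. *Nrg4*, an ERBB4 ligand, stood at 2.21 and 1.53 CPM, and *Errfi1*, a feedback inhibitor of EGFR, was 1.37-fold lower. The 11 measured ligands and receptors had a median of −0.34 (percentile 8.98). Genes induced by MAPK signalling had a median of −0.42 (percentile 2.47), divided between *Etv4* (2.00) and *Dusp4* (1.57), both higher, and *Egr1* (−1.89) and *Spry1* (−2.37), both lower. *Egr1* also belongs to the dissociation-stress genes, which were lower as a group. The EGF median turned to 0.59 under the stricter cell filter and to 0.19 when ISC, Wnt and regenerative genes were left out of the clustering. In TA-like cells alone the EGF median turned to 0.20 and MAPK stood at 0.04. Under the stricter filter *Egfr* (0.14) and *Errfi1* (0.87) also turned. In TA-like cells alone *Hbegf* was 1.24-fold and *Erbb3* 1.02-fold lower and *Btc* 5.49-fold higher. In all epithelial cells *Egfr* had the other direction, 2.17-fold higher in the KO, and *Btc* was 8.12-fold (6.67-9.99) higher.

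YAP and TAZ target genes were divided in KO progenitors. *Myof*, a membrane repair protein, and *Dock5*, a RAC activator, were higher at 2.20 and 1.06, and *Ctgf*, a secreted matrix protein and classic YAP target, stood at 0.51 on 6 control UMIs. *Cyr61*, its close relative, was −4.04 and *Amotl2*, a feedback inhibitor of YAP, −1.64. The 12 measured of 24 targets had a median of −0.04 (percentile 22.6). It turned to 0.36 in TA-like cells alone and to 0.91 with equal weights on both classes, and was −0.84 in cells thinned to 10000 UMIs. In all epithelial cells 9 of 13 targets were higher (0.60, percentile 99.99, and 0.92 with genes at 0 in a library set at their bound). Targets of mTORC1 and ATF4 had a median of 0.25 (percentile 93.0), with *Eif4ebp1*, a translation repressor, at 1.46 and *Psat1*, of serine synthesis, at 1.20 against *Slc7a5* (−1.10) and *Aldh18a1* (−1.20). Components of the mTOR complexes had a median of 0.24 (percentile 89.9), with *Lamtor1*, a lysosomal anchor of mTORC1, at 1.16, *Rictor*, the mTORC2 core, at −1.03 and *Deptor*, an mTOR inhibitor, at −1.81.

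Genes of cholesterol synthesis and glycolysis were higher in KO progenitors. All 20 measured cholesterol synthesis genes were higher (median 1.43, percentile 100), with *Fdps* at 2.37 and *Pmvk* at 2.12, and 12 of 14 glycolysis genes were higher (0.74, percentile 99.7), with *Hk1* at 2.83 and *Hk2* at −1.30. Fatty acid oxidation genes had a median of −0.06 (percentile 19.1). Genes of cell polarity had a median of 0.35 (percentile 94.9), with *Crb3*, an apical determinant, at 1.79, *Ezr*, a microvillus linker, at 1.49, *Pard6b*, a direct CDC42 partner, at −0.96 and *Ocln*, of tight junctions, at −0.85. G2/M genes had a median of 0.50 (percentile 99.99), led by *Tacc3* (1.31) and *Birc5* (1.20), whereas S phase genes had −0.77 (percentile 0), down to *Ung* (−1.86) and *Mcm6* (−1.52). The S phase median was 0.03 when ISC, Wnt and regenerative genes were left out of the clustering, and the G2/M median was −1.08 in TA-like cells alone. The unfolded protein response had a median of 0.68 (percentile 99.5), but 0.07 in TA-like cells alone, where cholesterol synthesis stood at 0.68 and OXPHOS turned to −0.16. In all progenitors p53 targets had a median of 0.19 (percentile 84.9), nuclear OXPHOS genes 0.20 (percentile 51.5), mitochondrially encoded genes −0.56 and ribosomal protein genes −0.26 (percentile 1.59).

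Other markers were measured beside these groups. The dissociation-stress genes had a median of −1.66 (percentile 0) in KO progenitors, with *Fosb* at −2.70 and *Nr4a1* at −2.69, whereas the heat shock genes *Hspa1a* (2.05) and *Hspa1b* (1.92) were higher. *Egr1* is in this list as well as among the MAPK-induced genes, so its fall cannot be assigned to either. Whether the lower *Cyr61* and *Hbegf* go with this list was not tested. TA markers had a median of 0.45, enterocyte markers 2.09, goblet markers 1.03, Paneth markers −3.07 (−4.61 at the bound), enteroendocrine markers −0.69, tuft markers 0.20, immune markers −2.21 and erythroid markers −1.29. In immune-like cells the Paneth marker *Itln1* stood at 136, 3.31 and 65.8 CPM in control, KO and rescue, and *Gm14851* at 79.4, 1.24 and 66.0. Free RNA of Paneth cells could therefore add to the Paneth medians of progenitors, here and in the rescue comparisons below. In TA-like cells alone dissociation stress stood at −0.87, TA markers at −0.57, Paneth markers at −1.54, enteroendocrine markers at 0.84, antimicrobial genes at 2.82 and MHC class II genes at −1.12. Genes of the proximal small intestine had a median of 1.48 (percentile 99.99), with *Cybrd1* and *Slc40a1*, which carry out duodenal iron uptake, at 4.80 and 4.23. Genes of the distal small intestine also had a positive median, 1.29 (percentile 99.6). The sex and strain list had a median of −3.76, because the control library was almost wholly from male and the KO library from female animals.

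**Figure D2:**
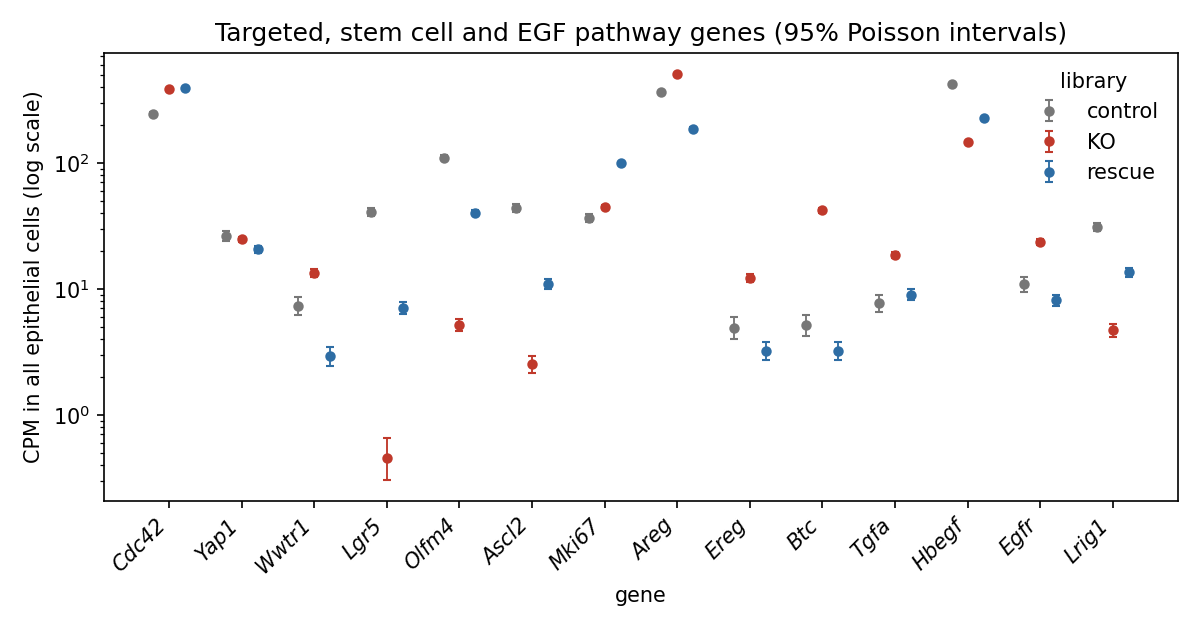
Expression of targeted, stem cell, cycling and EGF-pathway genes in all epithelial cells. The vertical axis is CPM on a log scale, the horizontal axis the gene, and colours are the control, KO and rescue libraries (1 library each). Error bars are exact Poisson 95% intervals. *Lgr5*, *Olfm4* and *Ascl2* are lowest in the KO library and between KO and control in the rescue library, and *Areg*, *Ereg* and *Btc* are highest in the KO library.

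Stem cell genes were higher in rescue than in KO progenitors. *Lgr5* stood at 14 CPM against 1.59, 8.83-fold (5.87-13.8) higher, *Olfm4* at 91.8 against 19.0, 4.83-fold (4.27-5.48) higher, and *Ascl2* at 24.5 against 8.74, 2.80-fold (2.31-3.42) higher. The 18 ISC markers had a median of 1.34 and the 14 Wnt targets 0.72 (percentile 99.95), with *Myc* at 1.69 and *Cd44* at −0.45. *Mki67* was 1.48-fold (1.40-1.55) higher, and all 35 G2/M genes (median 0.90), led by *Aurkb* (1.76) and *Nusap1* (1.75), and 28 of 30 S phase genes (0.67) were higher. The Notch and secretory fate genes had a median of 0.73 (percentile 99.9), with the secretory fate factor *Atoh1* at 1.67 and the ligand *Dll1* at 1.41. Under the stricter cell filter the Wnt median was 0.09, the ISC median 0.65 and the G2/M median 0.21, and *Mki67* turned to −0.15. When ISC, Wnt and regenerative genes were left out of the clustering the S phase median was −0.00 and the G2/M median 0.27. With cluster 14 added they were 0.20 and 0.47. The TA markers that name clusters share genes with both lists. They were raised for 18 of 18 in cluster 7, of most rescue progenitors, and 9 of 18 in cluster 5, of most KO progenitors. The cell cycle difference is therefore not independent of the naming.

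Genes of the regenerative program, and *Anxa10* and *Ctse*, were lower in rescue than in KO progenitors. All 18 regenerative genes were lower (median −2.65, percentile 0), including *S100a6*, 78.0-fold (71-85.9) lower, *Anxa1*, 199-fold (96.2-495) lower, and *Clu*, 147-fold (74.3-341) lower. *Ctse* was 179-fold (82.0-489) and *Sprr2a3* 172-fold (118-262) lower, and *Anxa10* stood at 165 CPM in the KO against 0.128 in the rescue. *Anxa3*, an annexin, was 60.7-fold, *Gm766* 48.3-fold and *Gsta4* 39.7-fold lower. *Gm8730*, an uncharacterised gene model, was 50.4-fold lower in the rescue, with 1776, 1504 and 29.9 CPM in control, KO and rescue. It was also 50.95-fold lower than the control in rescue immune-like cells, and the rescue file names another Cell Ranger version, so this is not read as a progenitor result. Among EGF ligands *Areg* was 6.04-fold (5.67-6.44), *Btc* 5.17-fold (4.0-6.76) and *Ereg* 3.56-fold (2.37-5.47) lower, *Tgfa* 1.76-fold and *Hbegf* 1.36-fold lower. *Egfr* was 1.76-fold (1.40-2.21) and *Lrig1* 1.64-fold higher, and *Errfi1*, the EGFR inhibitor, 2.38-fold (2.16-2.63) lower. The EGF ligands and receptors had a median of −0.47 (percentile 1.41) and MAPK-induced genes −0.43 (percentile 0.67), with *Etv4* at −2.70, *Dusp6* at −2.55, *Ccnd1* at 1.29 and *Spry2* at 0.93.

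YAP and TAZ targets had a median of −0.75 (percentile 0.15) in rescue over KO progenitors, with *F3*, the coagulation tissue factor, at −1.82, *Myof* at −1.55, *Cyr61* at 0.86 and *Nuak2*, a YAP-activating kinase, at 1.05. This median was −0.11 with members of at least 100 UMIs and 0.04 in cells thinned to 10000 UMIs. Targets of mTORC1 and ATF4 had a median of −0.41 (percentile 0.60), with *Chac1*, a glutathione-degrading enzyme, at −1.53 and *Trib3*, a stress pseudokinase, at −1.32 against *Aldh18a1* (0.53) and *Mthfd2* (0.34). The mTOR components had −0.24 (percentile 11.3), with *Eif4ebp1* at −1.12 and *Deptor* at 0.66. Glycolysis (−0.80), cholesterol synthesis (−0.63), fatty acid oxidation (−0.77) and polarity genes (−0.40, percentile 0.36) were lower as groups, with *Hk1* at −2.94 and *Hk2* at 1.43. Enterocyte markers had a median of −1.46, TA markers 0.68, goblet markers 0.06, Paneth markers 1.39, tuft markers 1.44, immune markers 1.26 and enteroendocrine markers 2.47, the last led by the hormone genes *Cck* (6.79) and *Gcg* (6.40).

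Antigen presentation set the rescue progenitors apart. *Cd74* was 291-fold (219-396) higher than in the KO, *H2-Ab1* 285-fold (159-571), *H2-Aa* 198-fold (104-433) and *H2-Eb1* 82.4-fold (58.3-121), all parts of the MHC class II system, and *H2-DMa*, its peptide loader, was 35.8-fold higher. *Psmb8* and *Psmb9*, of the interferon-induced immunoproteasome, were 28.5-fold (24.6-33.1) and 11.2-fold higher. *St3gal4*, a sialyltransferase, was 179-fold (81.8-488), *Ceacam10* 118-fold and *Tifa*, an adaptor of NF-kB signalling, 10.3-fold higher. All 7 MHC class II genes were higher (median 5.78), as were interferon response (0.75, percentile 100), antimicrobial (1.43) and inflammation genes (0.39, percentile 98.6). The dissociation-stress genes had a median of 0.50, p53 targets −0.37, the unfolded protein response 0.15, ribosomal protein genes 0.26, mitochondrially encoded genes 0.50, OXPHOS genes 0.16, proximal genes −1.11 and distal genes −0.66, the last turning sign under 3 settings.

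**Figure D3:**
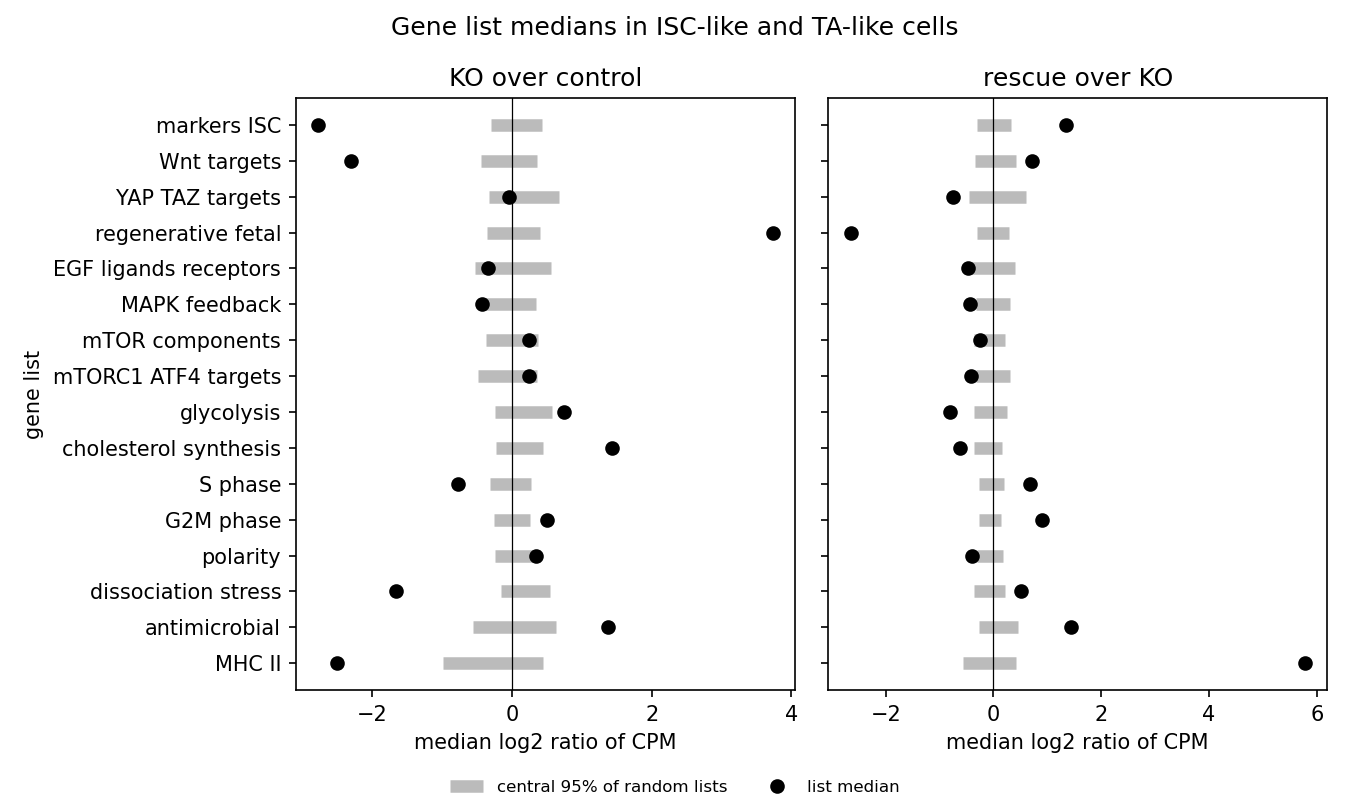
Median log2 ratio of each gene list in progenitors. The horizontal axis is the median log2 ratio, the vertical axis the list, and the panels are KO over control and rescue over KO (1 library each). Grey bars span the central 95% of 10000 matched random lists, a description of these libraries only. ISC, Wnt and regenerative lists lie on opposite sides of 0 in KO over control and rescue over KO.

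Rescue progenitors, of which 2 of 226 were ISC-like, had lower stem cell genes than control progenitors. The 18 ISC markers had a median of −1.60 and the 14 Wnt targets −1.68, with no member higher, Notch and secretory fate genes −0.59 and Paneth markers −2.38. *Gkn3*, a gastrokine of crypt base cells, was 8.77-fold lower. *Cyr61* was 9.25-fold lower, and so were other matrix and signalling genes, *Thbs1* (thrombospondin 1) by 15-fold, *Edn1* (endothelin 1) by 13.0-fold and *Gas6* by 10.5-fold. The YAP and TAZ targets had a median of −1.04 (percentile 0.030), EGF ligands and receptors −0.72 (percentile 0.020) and MAPK-induced genes −0.80. *AY761184* and *Gm15284* were 10.6-fold and 7.98-fold lower, again from a control level near that of immune-like cells, and the gene models *Gm8730* and *Gm10036* 59.5-fold and 15.5-fold lower. In TA-like cells alone medians were nearer 0 for ISC markers (−0.26), Wnt targets (−0.065) and EGF ligands and receptors (−0.067). This cannot show that the class mix was the cause, because whole clusters were named from the ISC markers themselves. Nearly all rescue progenitors lay in cluster 7, so any stem cells among them were counted as TA-like. The YAP and TAZ median was −0.49 without *Cyr61* and *Ctgf* and −0.38 with equal weights on both classes. Regenerative genes were slightly higher (0.50, percentile 99.6), but 0.10 in TA-like cells alone and −0.31 in all epithelial cells, and mTORC1 and ATF4 targets (−0.01) and mTOR components (0.02, and −0.02 and −0.04 with other scalings) were level. Under the stricter filter the Paneth marker median turned to 1.31 and *AY761184* to 0.08.

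Host defence genes were higher in rescue than in control progenitors. *Reg3b* was 439-fold and *Reg3g*, also a bactericidal lectin, 76.7-fold higher, with 24.1, 397 and 1850 CPM in control, KO and rescue. *St3gal4* was 69.2-fold and *Scd2* 68.9-fold higher, *H2-Aa* 20.3-fold, *H2-Eb1* 13.1-fold, *H2-Ab1* 12.0-fold and *Cd74* 7.72-fold higher. *1600014C10Rik*, an uncharacterised membrane protein, was 17.2-fold and *Hist1h2ap*, a replication-dependent histone, 12.2-fold higher. All 11 antimicrobial genes (2.24) and 7 MHC class II genes (2.94) were higher, the interferon response had 0.83 and inflammation −0.28. All 35 G2/M genes (1.31) and all 20 cholesterol synthesis genes (0.81) were higher, with S phase at 0.07, glycolysis 0.32, the unfolded protein response 0.64, OXPHOS 0.38, fatty acid oxidation −0.68, p53 targets −0.17 and polarity −0.08. The dissociation-stress genes had a median of −1.05, ribosomal protein genes −0.06, mitochondrially encoded genes −0.08, TA markers 1.13, enterocyte markers 0.02, goblet markers 1.26, enteroendocrine markers 2.46, tuft markers 1.12, proximal genes 0.05 and distal genes 0.73. In TA-like cells alone *Olfm4* was 1.29-fold (1.07-1.58) higher in the rescue than in the control (log2 0.36), *Lgr5* was not clearly apart (1.60-fold, 0.935-2.985, log2 0.62, on 14 control UMIs), and medians were −0.22 for G2/M, −0.01 for cholesterol synthesis, 0.10 for the unfolded protein response, 0.15 for TA markers, −0.54 for enterocyte markers, −0.02 for glycolysis, −0.18 for proximal genes and 4.95 for MHC class II. Under the stricter filter the TA (−0.14), goblet marker (−0.31) and S phase (−0.74) medians turned. The S phase median was also −0.33 with every barcode of at least 200 genes, −0.34 with at most 50% mitochondrial UMIs and −0.35 with cluster 14 added.

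In the epithelium as a whole, *Anxa10*, *Cybrd1* and *Ctse* had the highest KO over control log2 ratios among the named genes. *Anxa10* stood at 0 CPM in the control, 658 in the KO and 0.639 in the rescue, at least 4382-fold higher in the KO than in the control. *Ctse* stood at 0.10, 271 and 1.23 CPM, and *Cybrd1*, the duodenal ferric reductase, was 449-fold (324-641) higher. *Ly6d*, a surface protein of squamous cells, was 2516-fold (451-99390) higher against 1 control UMI, and *2010109I03Rik* 282-fold higher. *Mptx2*, a pentraxin of Paneth cells, was 1309-fold lower, and the defensin-type genes *AY761184* 441-fold, *Gm15292* at least 13080-fold and *Gm15299* at least 7207-fold lower. *Gm10104*, of the same kind, stood at 722 CPM in the control and at 1 UMI in the KO. All 14 Paneth markers were lower (median −7.08), ISC markers had −2.80, Wnt targets −1.95, enteroendocrine markers −2.71, S phase −1.12, G2/M −0.18, dissociation stress −1.54 and mTORC1 and ATF4 targets −0.39, while regenerative (2.83), cholesterol (1.05), glycolysis (0.96) and proximal genes (1.60) were higher. In the rescue over KO, *St3gal4* was 533-fold, *Mptx2* 647-fold and *Apol10a*, an apolipoprotein L gene, 289-fold higher, and *Gm15292* at least 2080-fold. *Anxa10* was 1030-fold, *Ly6d* 789-fold, *Cybrd1* 771-fold, *Sprr1a*, a barrier protein, 724-fold and *Ctse* 220-fold lower. The epithelial medians of rescue over KO were −2.57 for regenerative genes, −0.66 for YAP and TAZ targets, −0.62 for EGF ligands and receptors, 4.36 for MHC class II, 5.15 for Paneth and 1.48 for ISC markers. Against the control, *St3gal4* was 87.7-fold, *Scd2* 43.8-fold, *Reg3g* 32.1-fold, *Reg3b* 27.4-fold and *H2-Aa* 26.5-fold higher in the rescue, and *Gm8730*, *Thbs1*, *Vim* (vimentin) and *Nupr1* (a stress regulator) 44.4-, 17.9-, 15.4- and 11.9-fold lower.

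Enterocyte-like cells came mostly from cluster 18 in the control, 2 and 3 in the KO and 4 and 6 in the rescue, so different clusters stand side by side here. Regenerative genes had a KO over control median of 2.53 (2.89 at the bound), cholesterol synthesis 0.64, goblet markers 1.36 and proximal genes 1.11. Nuclear OXPHOS genes were lower in 67 of 72 cases (−0.54), including *Cox7a1*, a respiratory chain subunit, at −2.73, and ribosomal protein genes in 73 of 78 (−0.57). *Cdkn1a*, the p53-induced cell cycle inhibitor, stood at 123 CPM in the control, 376 in the KO and 157 in the rescue. MHC class II genes had a median of −1.34 and dissociation-stress genes −1.71. In rescue over KO the medians were 4.65 for MHC class II, led by *Cd74* (5.72), 1.57 for antimicrobial genes, −3.16 for regenerative genes, 1.13 for ribosomal protein genes, 0.55 for OXPHOS genes and 1.33 for dissociation stress.

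Detection of stem cell genes was compared at equal depth, with each cell thinned to 2000 UMIs. *Lgr5* was found in 7.12% (5.06-9.67) of control, 0.0657% (0.00166-0.366) of KO and 0.774% of rescue epithelial cells. *Olfm4*, in the same cells, was found in 13.9%, 0.591% and 5.64%, *Ascl2* in 9.23%, 0.526% and 1.88%, and *Mki67* in 5.19%, 5.13% and 8.84%. In immune-like cells, which do not express *Lgr5*, it was found in 0.326%, 0.334% and 0.123% and *Olfm4* in 0.762%, 0% and 0.369%. Median depths before thinning were 30095.5, 38781.5 and 40120 UMIs in epithelial cells and 5186, 5153 and 5022 in immune-like cells. The KO values rest on 1 cell with *Lgr5* in each population. With 4000 UMIs kept, *Lgr5* was found in 0.436% (0.160-0.947) of KO epithelial cells and 0 of 240 immune-like cells, so whether the KO cells stand above free RNA stays open.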

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

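Signals outside the main comparisons were examined in 3 places, all chosen after the data were examined. Cluster 16, macrophage-like cells led by *Lyz2*, *Fn1* and *Apoe*, held 30.4% (25.2-35.9) of the immune-like cells of the KO library, against 0.745% in the control and 2.82% in the rescue. Its genes also led the immune-like comparison of KO over control, where *Apoe* was 483-fold and the complement genes *C1qa*, *C1qb* and *C1qc* 561-, 684- and 390-fold higher and *Saa3*, an acute phase protein, at least 1061-fold higher. Immune-like cells of the control lay mostly in clusters with no KO cells, so these folds set different clusters side by side. With 1 library per genotype the cluster may be a feature of that library. Among epithelial barcodes over the mitochondrial limit (3763, 2462 and 1215), which the comparisons left out, the regenerative list had a KO over control median of 2.25 and the MHC class II list a rescue over control median of 3.65. Other lists there followed the progenitors only in part. The ISC markers (−2.19) and antimicrobial genes (1.55) of KO over control had the same direction, as had the MHC class II genes of rescue over KO (3.58). Others did not follow, such as the G2/M genes of KO over control (−2.15). The MHC class II median of KO over control was 0.0064, and the Wnt target median of rescue over KO was −0.72, against 0.72 in progenitors. In the rescue library 6.22% of epithelial cells held at least 2 Y-linked UMIs and no *Xist*, while most held *Xist*. A mix of animals of both sexes in that library is taken up below, where the number of cells with both kinds of UMI was 0.0171 of the number expected.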

How the results depend on the processing

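Main values stand in brackets after each first mention, and log2 ratios are of progenitors unless said. The alternatives with at most 50% mitochondrial UMIs, clustering without ISC, Wnt and regenerative genes, TA-like cells only, cluster 14 added and YAP targets without *Cyr61* and *Ctgf* were chosen after the data were seen. Of 429 alternative class shares 151 moved beyond the counting interval. Over 12 settings the goblet-like share was higher in the KO than in the control in 5 and lower in 7, the tuft-like share higher in 1 and lower in 9, the ISC-like share higher in the rescue than in the KO in 6 and lower in 2, and the enterocyte-like share higher in the rescue than in the control or the KO in 11 and lower in 1. Of 1973 list medians 848 moved and 22 turned, of 1887 single genes 855 moved and 29 turned, and of 108 thinned shares 72 moved. No value was given where a setting left too few members, such as MHC class II genes of KO over control under the strict filter. Unless a cause is stated, the cause was not tested. In 11 of 12 settings the ISC-like share was lower in the KO than in the control, and in 12 of 12 the TA-like share was higher. With every barcode of at least 200 genes, the ISC-like share was 2.84% in the control (21.8%) and 1.18% in the rescue (0.197%), and the TA-like share 1.20%, 7.81% and 14.1% in control, KO and rescue (6.33%, 18.7% and 22.1%). Rescue over KO gave −0.45 for YAP targets (−0.75), −0.16 for EGF ligands and receptors (−0.47), −0.52 for mTORC1 targets (−0.41) and 0.032 for *Cdc42* (−0.10), and epithelial rescue over control 0.070 for regenerative genes (−0.31) and 0.076 for mTORC1 targets (−0.24). With at most 10% mitochondrial UMIs and 1000 genes, which left 20, 145 and 69 progenitors, no cluster took the ISC-like name (0%, 0% and 0%), and the TA-like share was 11.4% in the control and 26.4% in the rescue. KO over control was then 0.27 for YAP targets (−0.04), 0.59 for EGF (−0.34), 0.54 for mTORC1 targets (0.25), −0.12 for G2/M (0.50), −0.96 for goblet markers (1.03), 0.22 for *Cdc42* (0.46), 0.14 for *Egfr* (−1.10), 0.87 for *Errfi1* (−0.45) and 0.42 for *Yap1* (−0.48). Rescue over KO was −0.42 for YAP targets, −0.56 for mTORC1 targets, 0.075 for *Cdc42*, −0.15 for *Mki67* (0.56) and −0.39 for *Yap1* (−0.11). Rescue over control was −0.012 for cholesterol synthesis (0.81), −0.14 for TA (1.13), −0.31 for goblet (1.26) and 1.31 for Paneth markers (−2.38), 0.085 for *AY761184* (−3.32), 0.33 for *Wwtr1* (−1.22), 0.033 for *Yap1* (−0.59) and 0.32 for epithelial regenerative genes. With at most 50% mitochondrial UMIs the ISC-like share was 10.8% in the control, the TA-like share 4.06%, 15.5% and 27.2%, rescue over KO −0.15 for EGF, −0.55 for mTORC1 targets and 0.030 for *Cdc42*, and epithelial KO over control −0.095 for *Mki67* (0.27). At 0.5 of the resolution the control ISC-like share was 25.2% and the TA-like share 8.85% in the control and 36.0% in the rescue, and at 2 times the resolution the KO TA-like share was 9.93%. With 20 components the rescue ISC-like share was 3.17% and the KO TA-like share 9.98%. With genes centred in each library the ISC-like share was 27.7%, 0% and 0% and the control TA-like share 0.314%. With each library alone the ISC-like share was 0% in KO and rescue, and the TA-like share 10.0% in the KO and 25.2% in the rescue. Without cell cycle genes the ISC-like share was 0% in the KO and 2.495% in the rescue, and the rescue TA-like share 31.1%. Without ISC, Wnt and regenerative genes the ISC-like share was 0% in KO and rescue and the KO TA-like share 10.3%. KO over control was −0.40 for YAP targets, 0.63 for mTORC1 targets, 0.029 for S phase (−0.77) and 0.27 for *Cdc42*, and rescue over KO −0.48 for YAP targets, −0.74 for mTORC1 targets, −0.00400 for S phase (0.67), 0.080 for *Cdc42*, −0.098 for *Mki67* and −0.32 for *Yap1*. With equal weights on ISC-like and TA-like cells, which by construction rest on 3 KO and 2 rescue ISC-like cells, KO over control was 0.91 for YAP targets, −1.08 for G2/M, 0.23 for *Cdc42*, −0.49 for *Mki67* (1.05) and 0.044 for *Yap1*. Rescue over KO was −1.07 for YAP targets, −0.34 for EGF, −0.58 for mTORC1 targets, −0.019 for *Lrig1* (0.68) and −1.804 for *Wwtr1* (−1.24), and rescue over control −0.038 for cholesterol synthesis, −0.21 for G2/M (1.31), 0.83 for *Gkn3* (−3.08), 0.15 for *Lgr5* (−2.79), −0.019 for *Mki67* (1.61) and 0.84 for *Olfm4* (−1.69). In TA-like cells only, KO over control was 0.36 for YAP targets, 0.044 for MAPK-induced genes (−0.42), 0.51 for mTORC1 targets, −1.08 for G2/M, 0.22 for *Cdc42* and −0.55 for *Mki67*, and rescue over control −0.011 for cholesterol synthesis, −0.22 for G2/M, 0.62 for *Lgr5* and 0.36 for *Olfm4*. With cells thinned to 10000 UMIs, KO over control was −0.84 for YAP targets, −0.70 for EGF, 0.46 for mTORC1 targets and 0.30 for *Cdc42*, and rescue over KO 0.038, −0.35 and −0.54 for the same 3 lists. With cluster 14 added, rescue over KO was −0.24 for EGF, −0.52 for mTORC1 targets and 0.038 for *Cdc42*. With the smaller CPM denominator, KO over control was 0.12 for mTORC1 targets and 0.32 for *Cdc42*, and rescue over KO −0.38 for EGF, −0.32 for mTORC1 targets and 0.000135 for *Cdc42*. Median-of-ratios scaling gave 0.13 for mTORC1 targets and 0.33 for *Cdc42* in KO over control. Members of at least 5 UMIs gave 0.23 for YAP targets in KO over control, and members of at least 100 gave −0.79, with −0.11 for YAP and −0.32 for mTORC1 targets in rescue over KO. A pseudocount of 5 gave −0.27 for YAP targets and −0.87 for *Wwtr1* in rescue over KO. With the control's class mix, which leaves out Paneth-like cells because the KO had 0, epithelial KO over control was 0.013 for Paneth markers (−7.08) by construction and −0.87 for *Mki67*. Epithelial rescue over control was then 0.18 for regenerative genes, 0.042 for ISC markers (−1.26), 0.044 for *Lgr5* (−2.36), −0.31 for *Mki67* (1.41) and 1.06 for *Olfm4* (−1.42).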

Other observations

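Of a gastric-type set of genes, chosen after its values were seen, *Anxa10* and *Ctse* were found in most KO epithelial cells and *Tff1*, *Gkn1*, *Cldn18* and *Dpcr1* in few. *Anxa10* was found in 88.2% of them, and in 29.0% of KO immune-like cells of far lower depth (5153 against 38781.5 UMIs). *Ctse* was found in 64.5%, against 10.6% of KO and 8.3% of control immune-like cells. *Tff1*, a trefoil peptide of stomach pit cells, was found in 9.99%, against 3.96% of KO immune-like cells, and stood at 55.8 CPM, at least 371-fold higher than in the control. *Gkn1*, a gastrokine, was at least 27.1-fold higher (7.55% of cells), *Cldn18*, the gastric claudin, stood at 7.32 CPM (4.32%) and *Dpcr1*, a mucin-like protein, at 12.3 CPM (8.1%, against 1.65% of KO immune-like cells). *Krt20*, a keratin of mature surface cells, was 7.64-fold (7.39-7.90) higher, *Lgals3*, a galectin of differentiated epithelium, 14.7-fold higher, and *Ada*, adenosine deaminase, 65.1-fold (61.6-68.9) higher. These 3 were found in 90.0%, 97.1% and 98.1% of KO epithelial cells, and in 32.0%, 84.5% and 91.4% of KO immune-like cells. Of 10 genes of stomach glands and pits, the 9 other than *Tff1* summed to 18.5 CPM in the control, 6.81 in the KO and 1.80 in the rescue, and the 7 that had not been seen higher in the KO to 17.9, 1.07 and 1.53. Antigen presentation was highest in the rescue, in progenitors (5.78 over KO) and enterocyte-like cells (4.65), while rescue immune-like cells were richer in *Igkc*, an antibody light chain, 145-fold over the control, in different clusters of each library. Within the rescue library MHC class II genes were lower in cells with *Xist* than in cells with Y-linked UMIs, by a log2 ratio of −0.86 in epithelium and −1.14 in deep enterocyte-like cells but not in TA-like cells (0.070), so they varied within that library.

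The lower ISC markers of the KO library were weighed against the cell filter, the sex of the animals and the part of the gut sampled, where the tests of the filter and of the gut part were chosen after the result was seen. Among barcodes over the mitochondrial limit the ISC marker median was also lower, at −2.19, which for these markers argued against removal of KO stem cells by the limit. The Wnt targets did not follow, at −0.27 (percentile 79.5). S phase (−2.03) and G2/M genes (−2.15) fell about as far, so the fall there was not particular to stem cell genes. In the rescue library ISC markers were slightly lower in the 580 cells with *Xist* than in the 59 with Y-linked UMIs. The median was −0.18 (counting interval −0.33 to −0.0056, percentile 0.24), a smaller fall than the bound set beforehand. Only 2 of 1013 rescue epithelial cells were ISC-like, and sex cannot be told apart from the animal there. This test therefore cannot decide whether sex lowered these markers in the KO library. The proximal list was higher in KO epithelium (1.60), and no reference for ISC markers along the gut was used here, so a different part of the intestine and the *Cdc42* genotype cannot be told apart. The distal list was also higher as a group in KO progenitors, so the shift there did not point to a single part. With 1 library each, the genotype may explain the pattern and stays a hypothesis.

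The higher regenerative and gastric-type genes of the KO library were weighed in the same way, where the tests of marker gap, stomach tissue and genotype were chosen after the result was seen. In the KO library the regenerative median of epithelial over immune-like and stromal-like cells was 0.28, between the bounds set beforehand, and 10 of 20 members were lower in epithelium, among them *Clu* (41.1 against 173 CPM), *Anxa1* (31.2 against 258) and *Ctsd* (301 against 2735), so free RNA could add to these members. As a set the list lay 8.42 above the immune and stromal markers, which argued against that compartment as the whole source, and in the rescue cells with *Xist* had no higher median than cells with Y-linked UMIs (−0.30). Stomach tissue carried over stays open for the gastric-type genes, since the other stomach genes had 0.0192 of the UMIs of *Tff1* when those seen higher in the KO were left out and 0.122 with them, on either side of the bound of 0.1. *Tff1* was also among the 10 leading genes of goblet-like cluster 12, so a ratio to *Tff1* cannot decide this. The list was lower in rescue than in KO progenitors (−2.65), which may come from the *Yap1* and *Wwtr1* alleles, but with 1 library each and other sexes this cannot be told apart from other differences between these libraries.

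Y-linked UMIs in part of the rescue cells were weighed with tests chosen after the result was seen. Of deep epithelial cells, 91.0% in the control held Y-linked UMIs without *Xist* and 97.6% in the KO held *Xist* without Y-linked UMIs, whereas in the rescue 8.83% were of the first and 86.8% of the second kind. With at least 2 UMIs of each kind required, 1 rescue cell held both against 58.6 expected from independence, a ratio of 0.0171, as cells of a male and of a female animal in 1 library would give. Cells free of *Xist* held a Y-linked UMI 42.9 times as often as cells with *Xist* (62 of 66 against 13 of 593, counting a single UMI), which argued against free RNA. Sex therefore differed between the control and KO libraries and could add to any difference between them.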
